A study of Canis lupus familiaris with 12 samples.

How the data were processed

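RNA of Madin-Darby canine kidney cells kept for 24 h at pH 7.0 or pH 7.4 had been labelled with Cy3 and hybridised to one-colour Agilent arrays for the dog, 6 arrays per group. The submitters' processing notes name Agilent Feature Extraction 10.7.3.1 as the program that read the scans. Per the file headers, the scanner files hold Cy3 intensity, as a processed signal, a median signal and a local background for every spot. The deposited value table holds log2 values, 1 column per array, and its 43593 entries cover 43553 of the array's gene probes. The scale and centring of that table are not stated by the authors. They were worked out by comparison: the table matched log2 of the processed signal minus the array's 75th percentile minus each probe's median over the 12 arrays, with a slope of 1.00 (lowest 0.999623) on every array. Its column medians were -0.112, -0.150, 0.225, 0.213, -0.226 and 0.0169 for pH 7.0 arrays 1 to 6 and 0.0200, -0.211, 0.213, 0.0789, -0.0860 and 0.0652 for pH 7.4 arrays 1 to 6. The direction of a ratio is not applicable to it, and columns of other samples number 0.

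The values analysed were computed from the scanner files. Control spots were left out, 128 outlier spots over the 12 arrays were set to missing, saturated spots were kept, and the spots of a probe were averaged on the log2 scale. Each array's 75th percentile was subtracted. A probe was tested where Feature Extraction called it well above background on at least 6 of the 12 arrays, whatever their group. The arrays were assigned to RNAs from the shared start of their file names, which follows the numbers in the titles: arrays 1 and 2 of a group hold biological replicate 1, arrays 3 and 4 biological replicate 2, and arrays 5 and 6 biological replicate 3. The 2 arrays of an RNA were averaged, so that 1 RNA extract was 1 replicate. The pairing of pH 7.0 and pH 7.4 extracts was checked across probes: deviations from the group mean correlated at 0.394, 0.637 and 0.807 within biological replicates 1 to 3, each higher than with an extract of another number. Each biological replicate also had its own slide and scan date, so this check cannot tell shared extraction from a shared slide. The precision is limited by the 3 pairs of extracts.

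The comparison was pH 7.0 minus pH 7.4 with the biological replicate as a block, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a constant prior). Its moderated test was two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The replicates are separate extractions from 1 cell line, and the p values refer to variation between those. The fit had 9.67 moderated degrees of freedom. Of the tested probes, 1 had a missing extract. Gene symbols came from RefSeq accessions without their version number, matched to an annotation of the dog assembly UU_Cfam_GSD_1.0. Other probes kept the identifier of the array. Gene lists were tested with limma's camera with a preset correlation of 0.01, two-sided, with 1 probe per gene, the brightest, and adjustment over the lists. There were 41 lists, of which 15 had the 5 tested members needed. The background was the named genes, since a list can only hold those. Members were also adjusted over the list alone, and that adjustment does not correct for the number of lists.

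The comparison, the lists, the naming rule and most alternatives were chosen before the data were examined. The rule took each gene by its brightest probe. In each direction it named 12 genes with 1 direction in all 3 biological replicates. These had passed or, where fewer passed, had the lowest unadjusted p. The rule also named the 4 members of lowest unadjusted p in each list described and a few cytokine genes named in advance. It gave 79 genes, of which 3 are not described here, and 20 more were singled out after their values were seen. A gene was said to disagree where another tested probe of it had the opposite sign. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.

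Alternatives covered the replicate block, the treatment of duplicate arrays, normexp background correction with an offset of 50, quantile and median scaling, the value table, the filters on dim probes and on outlier spots, the prior and weights of the fit, the thresholds, the mean of a gene's probes, the brightest unsaturated probe, and leaving out each biological replicate and each array. Camera with an estimated correlation and fry were also run. Normexp used the median signal because the files hold no mean signal. A block for the slide was not fitted separately, since slide and biological replicate were the same. Control spots, outlier spots and, outside the alternative without a filter, probes too dim for the test were left out, and the remaining columns of the scanner files were not used here.

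The fit was tested on simulated data of 27135 probes with 200 changed probes in each of 5 runs. With variances drawn from the fitted prior, limma recovered 0.4% of 1.5-fold, 3.6% of 2-fold, 93.6% of 4-fold and 99.2% of 8-fold changes, and 6.11% of its calls were false. With the moderated variances of the real probes it recovered 3.2%, 46.8%, 100% and 100%, with 13.7% false. Camera called the shifted cytokine list in 5 of 5 runs and 0 of 75 lists without a change. The simulated probes varied independently, while the estimated correlation between genes was 0.581 in the cytokine list and 0.792 in the interferon list, so these runs do not test the preset correlation.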

Results

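Madin-Darby canine kidney (MDCK) cells, an epithelial line derived from dog kidney tubule, were held for 24 h in medium at pH 7.0, made by lowering its bicarbonate, or in control medium at pH 7.4. The question was whether acid medium alters the expression of proinflammatory cytokine genes in these cells. The design had 3 biological replicates, whose RNA was extracted on different dates, and each gave 1 RNA from pH 7.0 and 1 from pH 7.4. Each of the 6 RNAs was hybridised to 2 one-colour Agilent arrays, which made 12 arrays, 6 per group. The 4 arrays of a biological replicate lay on 1 slide and were scanned on 1 date. Between 49.4% and 70.4% of the 43603 probes were well above background on an array, and the 75th percentile of the processed signal lay between 411 and 947. The 4 arrays of biological replicate 2 had the lowest shares, 49.4% to 54.1%, against 62.2% to 70.4% on the other arrays. Gene symbols could be given to 1484 probes, 3.40% of the array, so the named genes are a small part of what was measured. Changes are log2 differences, pH 7.0 minus pH 7.4, within the biological replicate, with the standard error of the limma fit (n = 3 pairs of RNAs).

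By the brightest probe, and with 1 direction in all 3 biological replicates, cytokine and chemokine genes led the named genes higher at pH 7.0. The gene with the largest estimate was CSF2, which encodes the growth factor GM-CSF: its signal was 8.64-fold higher (log2 change 3.11 ± 0.38, adjusted p = 0.0502), with changes of 1.83, 4.11 and 3.39 in the 3 biological replicates. The monocyte attractants CCL7 (2.79 ± 0.64), CCL8 (1.90 ± 0.31) and CCL2 (1.64 ± 0.35) and the mucosal chemokine CCL28 (1.38 ± 0.25) were also higher. Among the leading named genes lower at pH 7.0, each by its brightest probe, the lowest p belonged to PTGER2, a receptor for prostaglandin E2. It stood at -0.90 ± 0.22 (limma adjusted p = 0.172). None of these single genes passed an adjusted p of 0.05 over all probes.

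Of the 27136 probes tested, limma called 0 higher and 0 lower at an adjusted p under 0.05, while 3324 had an unadjusted p under 0.05, 1758 of them higher and 1566 lower, against 1356.8 expected by chance. Among the named genes, each by its brightest probe, 63 were higher and 21 lower at that unadjusted limma p. The named genes thus leaned higher, which bears on the counts of higher list members below. The smallest adjusted p, 0.0502, was shared by 19 probes, 13 higher and 6 lower. The 4 named ones were 2 probes of CSF2 and 2 of MMP9, a secreted gelatinase. Both of these MMP9 probes gave similar estimates, 2.21 ± 0.28 and 2.26 ± 0.30. The brightest MMP9 probe, which stands for the gene in the list tests, was saturated on 4 of 6 arrays at pH 7.0 and on 2 of 6 at pH 7.4, so no fold is given for it. At an adjusted p under 0.10 there were 48 probes higher and 23 lower. By any of their probes, the named genes among them were CSF2, CCL8, MMP9, NHLRC1 and OPTC. The count at an adjusted p under 0.05 moved with single replicates and arrays. It was 203 higher and 74 lower without biological replicate 1, 200 and 447 without biological replicate 2, 10 and 5 without pH 7.0 array 6, and 4 and 0 without pH 7.4 array 1.

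The 12 leading named genes on the higher side, of which 11 are described here, did not pass the threshold. They were ranked by their brightest probe, and the naming rule required 1 direction in all 3 biological replicates. Apart from those above, the described ones were CCL4, another chemokine (1.37 ± 0.29), ZP2, an egg coat glycoprotein (1.58 ± 0.30), MX1, an interferon-induced antiviral GTPase (1.46 ± 0.32), and COL2A1, a collagen chain (1.24 ± 0.30). The others were CLDN2, a claudin that forms cation channels in tight junctions (1.15 ± 0.29), and TNNI3, cardiac troponin I (1.11 ± 0.26). Adjusted p among these ran from 0.0502 for CSF2 to 0.174 for CLDN2. CCL7 owed much of its estimate to biological replicate 2 (5.42, against 1.52 and 1.43). Several of these genes were dim: at pH 7.4, CCL28 and CCL7 were well above background on 4 of 6 arrays each, and COL2A1 and CLDN2 on 3 of 6. With normexp background correction on the local backgrounds as given, CCL28, COL2A1 and CLDN2 took the opposite sign (-0.097, -0.29 and -0.33). With only the 8 and 3 spots on 2 arrays that lay more than 50 below their local background given the array's median background, they were 0.52, 0.36 and 0.35.

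**Figure D1:**
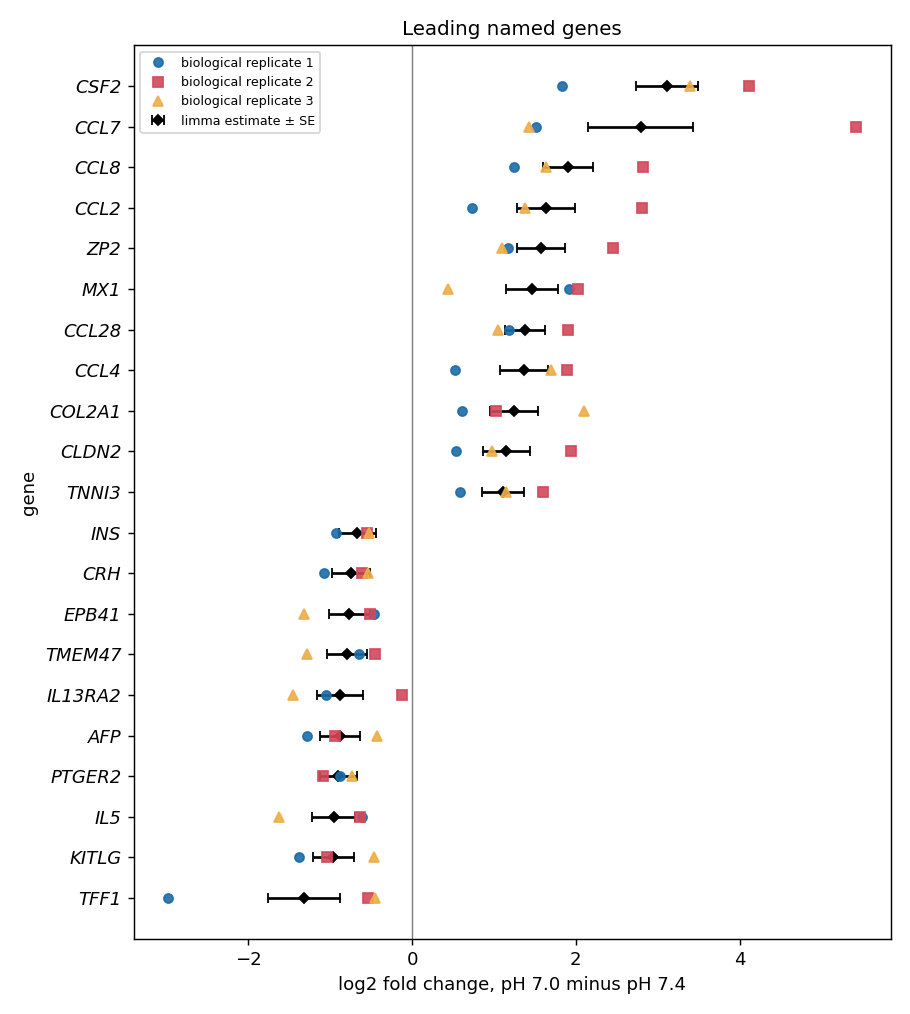
Log2 fold change, pH 7.0 minus pH 7.4 (horizontal axis), of the leading named genes described, 11 higher and 10 lower (vertical axis). Coloured points are the 3 biological replicates, each the mean of its duplicate arrays, and diamonds with bars are the limma estimate ± SE. All 3 points of every gene lie on 1 side of 0, as the naming rule required. The CCL7 estimate of 2.79 has 1 point at 5.42.

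The 12 leading genes on the lower side, of which 10 are described here, did not pass the threshold either. The naming rule again required 1 direction in all 3 biological replicates. TFF1, a secreted trefoil peptide, had the largest estimate, -1.32 ± 0.43, of which biological replicate 1 gave -2.98 and the others -0.54 and -0.45. KITLG, the ligand of the KIT receptor (-0.96 ± 0.25), and IL5, an eosinophil cytokine (-0.96 ± 0.26), came next. The other described ones were AFP (-0.88 ± 0.24), IL13RA2, a decoy receptor for interleukin 13 (-0.88 ± 0.28), TMEM47 (-0.79 ± 0.25), EPB41, a membrane skeleton protein (-0.77 ± 0.25), and CRH, a releasing hormone (-0.74 ± 0.23). INS, insulin, stood at -0.67 ± 0.23. On the brightest probes, the limma adjusted p in these 10 ran from 0.172 for PTGER2 to 0.277 for INS. AFP was well above background on 4 of 6 arrays in each group. Probes without a gene name lay among the leaders too. ENSCAFT00000022306 (2.31 ± 0.27) and ENSCAFT00000012596 (2.21 ± 0.27) were higher and TC56828 (-2.48 ± 0.32) and ENSCAFT00000000367 (-2.38 ± 0.28) lower at pH 7.0, each with an adjusted p of 0.0502.

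Proinflammatory cytokines and chemokines as a group rose against the other named genes at pH 7.0. Of the 15 members tested, 13 were higher and 2 lower, and 8 were higher in all 3 biological replicates. Of all tested probes, 33.7% had 1 direction in all 3. The mean log2 change of the list was 1.06 and its median 0.81. The list moved against the other genes in camera with a preset correlation of 0.01 (adjusted p = 5.2e-06), and this call was lost at adjusted p = 0.790 with an estimated correlation. Over all probes 0 members passed limma's threshold, and 7 had an unadjusted p under 0.05. Adjusted over the list alone, the same 7 passed and all of them rose: CSF2, CCL8, CCL28, CCL4, CCL2, CCL7 and CXCL8, the neutrophil attractant interleukin 8 (0.86 ± 0.30). Without the replicate block 1 member passed over the list alone. Median changes of the list by biological replicate were 0.52, 1.91 and 0.43, and without biological replicate 2 its mean was 0.56. Over all probes 6 members passed without biological replicate 1, 3 without biological replicate 2, and 1 each without pH 7.0 array 6 and without pH 7.4 array 1. The mean was 0.53 under normexp with local backgrounds as given, where 3 members passed over the list alone, and 0.54 when the dim members were taken in (adjusted p = 0.000306).

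Several cytokines of the group did not follow the leaders. CCL5 (0.81 ± 0.44) and CCL20 (0.45 ± 0.50), both attractants of lymphocytes, differed in sign between biological replicates, with 2.31 and 2.43 in biological replicate 2 against -0.62 and -0.65 in biological replicate 3. CCL5 had the opposite sign, -0.37, under normexp with local backgrounds as given. TNF, the tumour necrosis factor, stood at -0.096 ± 0.22 (adjusted p = 0.908), and was well above background on 4 of 6 arrays at pH 7.0 and 5 of 6 at pH 7.4. The remaining tested members were CCL27 (0.56 ± 0.26), LTB (0.44 ± 0.32), CXCL10 (0.74 ± 0.65), CCL17 (0.25 ± 0.23) and TNFSF10 (-0.33 ± 0.31), and they were singled out after their values were seen. The CCL17 probe was saturated on 2 of 6 arrays at pH 7.0. CXCL10, an interferon-induced chemokine, was 2.10 and 2.05 in biological replicates 1 and 2 and -1.94 in biological replicate 3. Another 18 cytokine genes of the list had probes that were too dim for the test, among them IL1B, with 0 of 12 arrays above background, and IL6, with at most 2. IL1A, the alarm cytokine interleukin 1 alpha, was well above background on 5 of 6 arrays at pH 7.0 and 0 of 6 at pH 7.4, which makes it at least 1.74-fold higher. Fitted without the filter on dim probes its change was 1.85 ± 0.28 (adjusted p = 0.114).

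**Figure D2:**
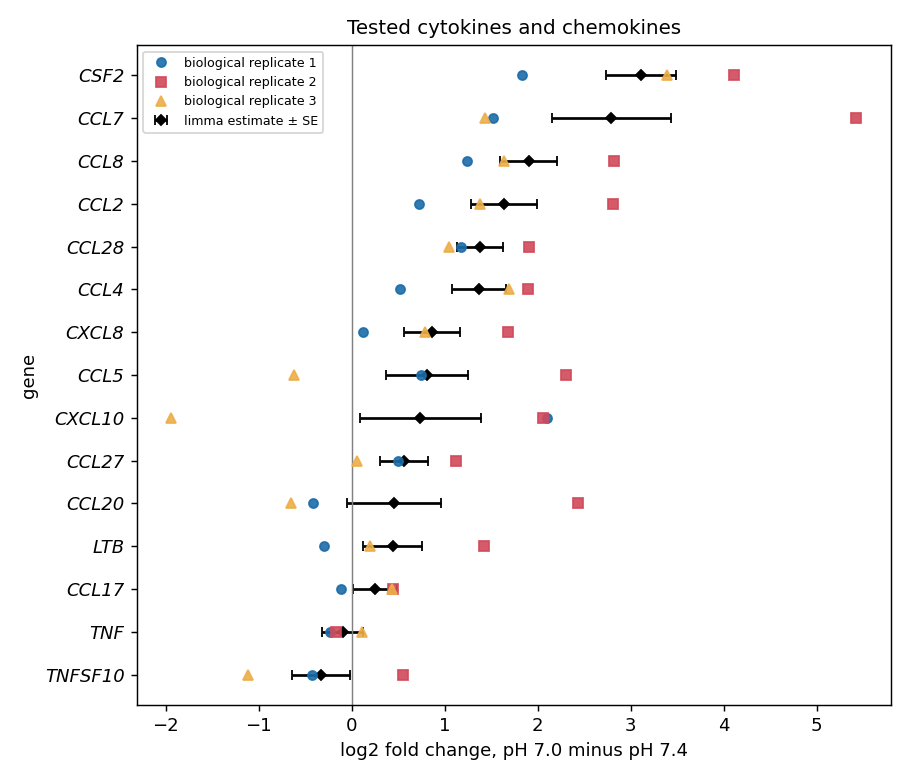
Log2 fold change, pH 7.0 minus pH 7.4 (horizontal axis), of the 15 tested cytokine and chemokine genes (vertical axis). Coloured points are the 3 biological replicates, each the mean of its duplicate arrays, and diamonds with bars the limma estimate ± SE; 8 genes have all 3 points above 0, and the other 7, CCL5, CCL20 and CXCL10 among them, have points on both sides.

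Interferon-response genes rose as a group too. All 6 tested members were higher at pH 7.0, 4 of them in all 3 biological replicates, with a mean log2 change of 0.86 and a median of 0.77. Camera called the list at adjusted p = 0.000439 with the preset correlation, and this was lost at adjusted p = 0.790 with an estimated correlation. Over all probes 0 members passed in limma, 4 had an unadjusted p under 0.05, and these 4 rose when adjusted over the list alone. They were MX1, the oligoadenylate synthetases OAS1 (1.02 ± 0.27) and OAS2 (0.87 ± 0.33), which sense viral RNA, and the immunoproteasome subunit PSMB8 (0.68 ± 0.25). OAS3 (0.57 ± 0.26) and PSMB9 (0.57 ± 0.27), which complete the list and were singled out after their values were seen, did not pass. Biological replicate 3 had smaller changes, with a list median of 0.27 against 0.93 and 1.34 in the others. There OAS2 and OAS3 were -0.14 and -0.063.

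**Figure D3:**
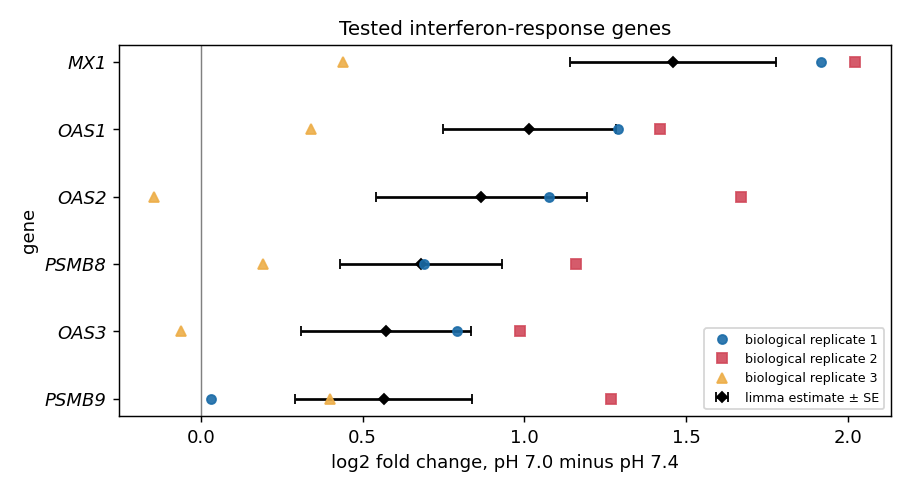
Log2 fold change, pH 7.0 minus pH 7.4 (horizontal axis), of the 6 tested interferon-response genes (vertical axis). Coloured points are the 3 biological replicates, each the mean of its duplicate arrays, and diamonds with bars the limma estimate ± SE; the points of biological replicate 3 are the lowest for every gene but PSMB9, and those of OAS2 and OAS3 lie below 0.

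Other signalling lists of inflammation had no call in camera. In the NF-kappaB list 4 of 5 tested members were higher (adjusted p = 0.487), among them the apoptosis inhibitor BIRC3 (0.53 ± 0.24) and the NF-kappaB subunit NFKB1 (0.50 ± 0.23), while BIRC2 stood at -0.41 ± 0.23. MMP9, also of that list, entered the test through its saturated probe, and with the brightest unsaturated probe of each gene the list had no call either (adjusted p = 0.193). With normexp on local backgrounds as given the NF-kappaB list passed (adjusted p = 0.0374), again at the preset correlation. On the values as reported it had an adjusted p of 0.790 with an estimated correlation. PTGS2, the inducible cyclooxygenase of that list, was at 0.037 ± 0.23. Toll-like receptor and inflammasome genes split into 3 higher and 3 lower (adjusted p = 0.491). HMGB1, a nuclear protein that acts as an alarm signal outside cells, was at 0.67 ± 0.24 on its brightest probe and at -0.056 on its other probe, so its probes disagreed. The receptor TLR1 (0.57 ± 0.22), the inflammatory caspase CASP4 (0.60 ± 0.24) and the receptor TLR9 (-0.35 ± 0.29) were dim, and the first 2 turned negative (-0.44 and -0.59) under normexp as given. Cytokine receptors and antagonists had 3 of 6 members higher (adjusted p = 0.487), with a mean of -0.11, a median of 0.018 and a test direction of down. LIFR (-0.28 ± 0.24), ACKR3 (0.23 ± 0.22) and SOCS3 (0.21 ± 0.28) were close to 0 beside IL13RA2, and the ACKR3 probe was saturated on 1 array at pH 7.4. In the prostaglandin and eicosanoid list 5 of 7 members were higher (adjusted p = 0.491), with a mean of -0.061, a median of 0.076 and a test direction of down. Adjusted over the list alone, PTGER2 fell. PTGER4 (-0.31 ± 0.22), PTGDS (0.38 ± 0.27) and the prostaglandin carrier SLCO2A1 (0.17 ± 0.22) did not pass.

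Genes of renal acid handling were few among the named ones. Of 6 tested acid-base transporters and carbonic anhydrases, 2 were higher and 4 lower (camera adjusted p = 0.413), among them the carbonic anhydrases CA2 (-0.37 ± 0.23) and CA1 (-0.32 ± 0.23) and the ammonia channel RHBG (-0.33 ± 0.26). RHAG, of the same channel family and counted among the higher ones, was saturated on all 12 arrays, so no fold is given. Without its saturated probes 1 of 5 members was higher and 4 lower (adjusted p = 0.193). GLUL, glutamine synthetase, was the only tested member of the ammoniagenesis and gluconeogenesis list, and it stood at 0.84 ± 0.22 with 0.85, 0.79 and 0.88 in the 3 biological replicates (adjusted p = 0.184). Adjustment over the list alone corrects nothing for a list of 1 gene, and left GLUL at its unadjusted limma p of 0.00339. GLUL was singled out after its values were seen. The 2 tested genes of the vacuolar H+-ATPase were higher, 1 of them with an unadjusted limma p under 0.05, and 0 passed over all probes. The 3 tested proton sensors, also named after their values were seen, were lower without passing: CASR, the calcium-sensing receptor (-0.45 ± 0.23), and the channels TRPV4 (-0.25 ± 0.22) and TRPV1 (-0.14 ± 0.29), whose other probe had the opposite sign.

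Junction and matrix lists were not called. Among epithelial junction and polarity genes 6 of 7 were higher (camera adjusted p = 0.487), and CLDN2 rose when adjusted over the list alone. The tight junction proteins OCLN (0.26 ± 0.23) and CGN (0.24 ± 0.23) did not. CTNNB1, beta-catenin, was saturated on all 6 arrays at pH 7.0 and 3 at pH 7.4, so no fold is given for its brightest probe. Its 3 unsaturated probes were higher in all 3 biological replicates without passing over all probes, at 1.31 ± 0.27, 0.92 ± 0.25 and 0.67 ± 0.22 (adjusted p from 0.127 to 0.264). Among 8 extracellular matrix and fibrosis genes 5 were higher (adjusted p = 0.549). TIMP2 (0.50 ± 0.24) and TIMP1 (0.58 ± 0.35), inhibitors of matrix proteases, and COL1A1 (0.43 ± 0.26) did not pass.

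Stress and metabolic lists were not called. In the list of endoplasmic reticulum chaperones and folding 4 of 5 members were lower (adjusted p = 0.135), with SEC11C at -0.45 ± 0.22, the translocon subunit SEC61B at -0.34 ± 0.24 and SSR1 at -0.31 ± 0.23. That list passed with the mean of a gene's probes (adjusted p = 0.0408), with the brightest unsaturated probe of each gene (adjusted p = 0.0228) and with normexp after the local backgrounds marked as outliers were set to the array's median (adjusted p = 0.0223). These calls rest on the preset correlation, and on the values as reported the list had an adjusted p of 0.790 with an estimated one. The brightest probe of the chaperone HSP90B1 was saturated on 3 and 5 of 6 arrays. Its unsaturated probe was lower in all 3 biological replicates without passing, at -1.15 ± 0.31 (adjusted p = 0.205). In the lysosome and autophagy list 8 of 10 genes were higher (adjusted p = 0.487), led by TPP1 (0.64 ± 0.29), GUSB (0.40 ± 0.25), CTSA (0.37 ± 0.23) and GLB1 (0.33 ± 0.25), and CTSA had a probe of opposite sign. NRF2 and antioxidant genes had 5 of 8 higher (adjusted p = 0.795), with MT2A, a metallothionein, at 0.43 ± 0.27, ABCC2 at 0.27 ± 0.24 and catalase, CAT, at 0.23 ± 0.22. FTL was saturated on 6 and 5 of 6 arrays. In the p53 and cell death list 6 of 8 were higher (adjusted p = 0.549), among them the pore-forming protein BAK1 (0.78 ± 0.23), BCL2L1 (0.22 ± 0.23), MDM2 (0.22 ± 0.25) and CASP9 (0.20 ± 0.26). Fatty acid oxidation and PPAR genes divided into 3 higher and 3 lower (adjusted p = 0.903). Their mean was 0.075 and their median 0.0082, with a test direction of down in camera and up in fry. Camera sets a list against the other named genes, which leaned higher. PPARD was at 0.54 ± 0.23, PPARG at -0.27 ± 0.24, PPARA at 0.27 ± 0.35 and the uncoupling protein UCP3 at -0.11 ± 0.29.

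Markers of fibroblasts, endothelium, leukocytes and segments of the kidney tubule were examined for changes between the groups. These changes cannot show a mixed culture, since other cells present equally in both groups would give no change. Markers of fibroblasts and endothelium had 3 of 5 members higher (camera adjusted p = 0.863), with VWF at 0.17 ± 0.31 and COL1A2 at -0.21 ± 0.23, of which 2 other probes had the opposite sign. S100A4 was saturated on 6 and 4 of 6 arrays. The other marker lists had 2 tested genes each, too few for a set test, and these genes were named after their values were seen. Leukocyte markers stood at 0.31 ± 0.22 for DLA-DRA and -0.0093 ± 0.23 for CD8A, proximal tubule markers at 0.16 ± 0.36 for CUBN and 0.077 ± 0.25 for SLC5A2, and collecting duct and distal tubule markers at -0.69 ± 0.32 for ATP1B1 and -0.024 ± 0.23 for AVPR2. No marker passed in limma over all probes or over its list alone, and none of the 2-gene lists' members had an unadjusted p under 0.05.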

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

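The tests of compressed changes, of dim-spot noise, of the spread of dim probes and of the other splits of the extracts were chosen only after the result was seen. IL1A, which encodes the cytokine interleukin 1 alpha, was left out of the comparison because its probe was dim. It is listed here because that probe was well above background on 5 arrays of pH 7.0 and on 0 arrays of pH 7.4.

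The cytokine and chemokine list and the interferon list were set beside other splits of the 6 extracts. There are 10 splits into groups of 3, too few for a share under 0.05. Of these, 4 part all 3 pairs of extracts, the real one included. The other 6 part 1 pair, and under the replicate block they are the pH difference of that biological replicate alone, each counted 2 times, so they are no measure of chance. Each other split that parts all 3 pairs reverses 1 biological replicate and keeps the pH difference of the other 2. Such splits are no clean measure of chance either. In both lists the smallest p among them came from the split that reverses biological replicate 3. For the cytokine list 3 of 10 splits gave as small a camera p, and 2 of these were the change of biological replicate 2 alone (6.1e-12). The real p was 3.5e-07 and the smallest other that parts 3 pairs 1.3e-05. For the interferon list 4 of 10 splits gave as small a p, and 2 of these again were biological replicate 2 alone. The real p was 5.9e-05 and the smallest other that parts 3 pairs 1.3e-05. At an unadjusted p under 0.05 the real split had 3324 probes and was the 1 split with as many, with 2106 in the highest other, a single biological replicate, and 1032 in the highest other that parts 3 pairs. Past limma's adjusted threshold the real split had 0 probes, so 10 of 10 had as many. The highest other had 29, the change of biological replicate 1 alone, and the others that part 3 pairs had 0.

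OAS1, OAS2, MX1 and the other interferon-response genes except PSMB9 had their smallest changes in biological replicate 3. A single deviating array there was argued against: the highest list median among its 4 array pairings was 0.33, below the lowest of the 8 pairings of the other biological replicates, 1.08. Compressed changes on its slide stay open: its median absolute change over all probes was 1.26 times the mean of the others, but its duplicate arrays also differed more, 1.34 times the mean of the others, and noise alone raises that measure. A higher level at pH 7.4 stays open too: it was higher by 0.30 on the log2 scale against a missing change of 0.87, while the level at pH 7.0 differed by -0.48. A biological difference between extraction days may also underlie the pattern and was not tested.

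The pH 7.4 array 1 lay apart from its duplicate, with a correlation of deviations of 0.0328 against 0.58 to 0.71 for the other pairs. A spatial trend taking a larger share of variance than in the other pairs was argued against. The share taken by blocks of neighbouring spots was 0.129 times the highest of those pairs. That share shrinks as other noise grows. The median difference among middle probes was 0.449 here, against 0.138 in the pair with the highest share, from pH 7.0 biological replicate 2. A trend of equal absolute size therefore stays open. A mislabelled array stays open: its correlation with the duplicate exceeded the best other by 0.00361, within the 0.0261 that separated the 2 arrays of that other RNA. The outcome set beforehand counted any difference above 0 against mislabelling and did not include that margin. The duplicate, pH 7.4 array 2, correlated better with pH 7.0 array 2 (0.984), pH 7.4 array 4 (0.978) and pH 7.0 array 1 (0.974) than with pH 7.4 array 1 (0.972). Noise of dim spots may contribute, since the difference within the pair was 0.849 times the highest of the other pairs among the brightest of 3 equal classes of probes and 1.66 times among the dimmest. No biological explanation was tested, as both arrays held 1 RNA.

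The number of calls for single genes such as CSF2 moved with the filter on dim probes and with the prior. Larger spread of dim probes is a possible explanation that was not settled: the median residual SD of the dimmest of 3 equal classes of tested probes was 1.45 times that of the brightest, 0.312 against 0.216, between the bounds set for and against it. No biological explanation was tested for this pattern.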

How the results depend on the processing

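The trend alone and the robust prior alone in eBayes, the background of all tested probes, both normexp alternatives with corrected local backgrounds, and the brightest unsaturated probe of each gene were chosen after seeing the data, as was recording the members passing over the list alone and the interferon shift under the alternatives chosen earlier. The rise of the cytokine and chemokine list (mean log2 change 1.06) and of the interferon list (0.86) kept direction and camera call under every alternative to the fit, scaling, filter or background. The exceptions were tests of the lists that do not preset the correlation: with an estimated correlation the means 1.06 and 0.86 had an adjusted p of 0.790 each, and with fry 0.422 each, and 0 of the other lists were called. Over all alternatives the adjusted p ran from 3.9e-17 to 0.790 for the cytokine list and from 3.2e-06 to 0.790 for the interferon list. With no filter on dim probes, which brings the dim cytokine genes into the list, the cytokine mean was 0.54 (adjusted p = 0.000306). Leaving out 1 biological replicate or array, the cytokine mean ran from 0.56 to 1.33 and the interferon mean from 0.58 to 1.19. The gene set tests of the other lists had 1 call, the interferon list, and 2 under normexp as given, which added the NF-kappaB list, and 2 each under both corrected versions of normexp, with the mean of a gene's probes and with the brightest unsaturated probe, which added the endoplasmic reticulum chaperones. The cause was not tested, except for normexp.

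Probes past the threshold, 0 higher and 0 lower with limma (3324 at an unadjusted p under 0.05), were more under several alternatives. There were 396 higher and 294 lower with the 12 arrays and the RNA extract as a random block, and 819 and 669 with 12 arrays as independent, which counts duplicates as replicates. There were 10 and 4 with normexp as given, 17 and 7 with the median of the probes above background on all arrays, and 16 and 6 with arrayWeights. The prior gave 122 and 70 with trend and robust prior together, 85 and 50 with trend alone and 12 and 6 with the robust prior alone. The stricter filter, well above background on all 12 arrays, gave 90 and 44, the looser adjusted p under 0.10 gave 48 and 23, and an unadjusted p under 0.05 with a change of at least 1.5 times, which has no correction, gave 1408 and 1308. The remaining alternatives kept 0 and 0. Leave-one-out fits ran from 0 to 203 higher, the latter without biological replicate 1, and from 0 to 447 lower, the latter without biological replicate 2. The looser thresholds and the arrays counted as independent pass more by construction. The fit with the extract as a random block also takes its residual degrees of freedom from the 12 arrays, which favours more calls. How much of its rise that gives was not tested. For the remaining alternatives and the leave-one-out fits the cause was not tested.

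Cytokine and chemokine list members called over all probes were 0, and 6 with the extract as a random block, 6 with 12 arrays as independent, 2 with normexp as given, 1 with the median of the probes above background on all arrays, and 4 with the filter of all 12 arrays. They were 3 with trend and robust prior, 3 with trend alone, 1 with arrayWeights, 2 at an adjusted p under 0.10 and 7 at the unadjusted threshold. Leave-one-out fits called 0 to 6. Over the list alone 7 passed, 1 without the replicate block, 3 with normexp as given and 6 to 9 in leave-one-out fits. CSF2 had an adjusted p from 2.0e-09 to 1.00 over the alternatives, and passed in 11 of 35.

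Single genes gave 3435 values under the alternatives for 99 genes: 3274 kept direction and side of the threshold, 77 passed with the same direction and 84 took the opposite sign, and 63 genes never did so. With normexp as given the sign turned for CCL28 (-0.097), COL2A1 (-0.29), CLDN2 (-0.33), TLR1 (-0.44), CASP4 (-0.59), NR4A1 (-0.45), TPP1 (-0.38), OAS3 (-0.025), TIMP2 (-0.0090) and CCL5 (-0.37). It also turned for PTGDS (-0.39), CXCL10 (-0.093), BCL2L1 (-0.43), SLCO2A1 (-0.20), SOCS3 (-0.72), PPARA (-0.49) and SLC5A2 (-0.48). Here a cause shows: on pH 7.4 arrays 3 and 4, 8 and 3 spots lay more than 50 below their local background, 0 on the other arrays, and the fitted normexp SD was 424 and 409 against at most 2.88. That moved the median change of all probes to -0.19, against 0.012 as reported, so directions under it are relative to that shift. With only those 8 and 3 spots given the array's median background, the SDs were 1.61 and 6.80 and the median change 0.027, and the genes that turned were RHBG (0.036), TRPV1 (0.031), TNF (0.086), AVPR2 (0.029) and CD8A (0.027). With every local background marked as an outlier, 242 to 1249 per array, set to the median, the SDs were 1.58 and 2.10 and the median change 0.030, and RHBG (0.043), TRPV1 (0.037), TNF (0.094), AVPR2 (0.034) and CD8A (0.034) turned.

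For the other alternatives the cause was not tested. The first array of each duplicate alone turned CCL17 (-0.0027), TRPV1 (0.45), SLC5A2 (-0.093) and PTGS2 (-0.011), and the second alone RHBG (0.041), TNF (0.14), UCP3 (0.017), AVPR2 (0.17) and CD8A (0.23). Quantile normalization turned PTGS2 (-0.11) and CD8A (0.032), arrayWeights UCP3 (0.015), and the mean of a gene's probes COL1A2 (0.0098) and TRPV1 (0.069).

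Leaving out 1 biological replicate or array, values ran across 0 for LTB (-0.050 to 0.81), TLR9 (-0.65 to 0.066), TNFSF10 (-0.77 to 0.062), BCL2L1 (-0.075 to 0.52), CCL20 (-0.54 to 1.01) and SOCS3 (-0.055 to 0.57). They did so too for PPARA (-0.31 to 0.72), CASP9 (-0.12 to 0.41), VWF (-0.28 to 0.54), TRPV1 (-0.44 to 0.25), CUBN (-0.21 to 0.79) and TNF (-0.25 to 0.057). The rest were UCP3 (-0.50 to 0.20), SLC5A2 (-0.12 to 0.33), PTGS2 (-0.081 to 0.19), AVPR2 (-0.19 to 0.14) and CD8A (-0.15 to 0.16). The cause of these was not tested. The saturated probes of RHAG, FTL and HSP90B1 give no measure of change, and their computed differences also crossed 0: RHAG had -0.15 and FTL -0.17 with the first array of each duplicate alone, and in leave-one-out fits RHAG ran from -0.046 to 0.25, FTL from -0.069 to 0.26 and HSP90B1 from -0.46 to 0.16.

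A block for the slide was not run, since each slide held 1 biological replicate. Signal over background limits the dim genes: IL1B and IL6 were below it on most or all arrays, so a fall in them, or a rise that stayed under background, was not detectable here.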

Other observations

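None of the tests in this part was chosen only after the result was seen, while the genes of the small lists were singled out after their values were seen.

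Lists with fewer than 5 tested members were too small for a set test. They numbered 26, 5 of them with none and 21 with 1 to 4, and held 42 different genes, 27 higher and 15 lower at pH 7.0. In limma 0 of these passed over all probes and 5 had an unadjusted p under 0.05. The 5 included GLUL and the vacuolar H+-ATPase gene described above. NR4A1, an immediate early nuclear receptor, stood at 0.86 ± 0.34 (adjusted p = 0.356), with -0.29 in biological replicate 1, 1.60 in biological replicate 3 and -0.45 under normexp as given. HSPB8, a small heat shock protein, stood at 0.74 ± 0.27 (adjusted p = 0.315), with 0.53, 0.28 and 1.40. PDGFB, a growth factor, stood at 0.76 ± 0.23 (adjusted p = 0.238), with 1.07, 0.43 and 0.79, and it passed over the list alone. The other 2 tested members of the growth factor list were lower in all 3 biological replicates.

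Separate probes of 1 gene were compared to see whether changes belong to the transcript and not to 1 probe. Over 225 named genes with at least 2 tested probes, the changes of the brightest and the next probe correlated across genes at r = 0.803 (rho = 0.813), and genes are not independent replicates. Of these genes 42 had opposite signs, 6 of them among the 59 with an unadjusted p under 0.05. The correlation goes with changes shared by the probes of most of these genes. HMGB1, COL1A2, CTSA and TRPV1 were among the described genes with probes of opposite sign. Both probes of a gene read the same RNAs, so variation between extracts alone would also correlate them, and no effect of pH follows.

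Chemokine genes often lie beside each other in the genome, so members of the cytokine list with a list gene within 5 genes were compared with the rest. The 9 such members had a mean log2 change of 1.07 and the other 6 a mean of 1.05. The difference of 0.018 had an exact two-sided permutation p of 0.981 over 5005 assignments, and this number of genes does not exclude a larger difference.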
